A study of Homo sapiens with 18 samples.

How the data were processed

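RNA from 18 samples of FaDu and RS-FaDu cells was measured on single-colour (Cy3) Agilent microarrays that carry probes for long non-coding RNAs and messenger RNAs, 3 arrays for each of 6 groups. FaDu is a human hypopharyngeal carcinoma cell line, and RS-FaDu is a radioresistant line that was derived from it by repeated fractions of radiation. Both lines had received 4 Gy, and the sample labels place the groups at 0, 24 and 48 h from then. The overall description of the series gives 2 h in place of 24 h, while every sample label and the treatment protocol give 24 h, which was used here. No unirradiated sample is labelled, so the 0 h arrays are irradiated cells taken at once and not an untreated control. The labels do not say whether the 3 replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

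Per the labels, RNA was extracted with TRIzol and amplified by a linear method before labelling. The deposited scanner files hold the intensity of each spot, which the authors obtained with Agilent Feature Extraction. The labels give its version as 10.7 and the file headers give 11.5.1.1, and this difference was not resolved. Per the file headers, the processed intensity is background-subtracted and spatially detrended within an array, with no scaling between arrays, on a probe grid built on hg19. The deposited value table holds log2 values, which the authors had centred so that the 75th percentile of each array is 0. Its values were checked against log2 of the scanner intensities, and the Pearson correlation over probes was 0.99856 or higher on each array. The value table served only as an alternative.

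Spots marked as non-uniform or population outliers, between 0.772% and 1.17% of the spots of an array, were left out, and the remaining spots of a probe were averaged as log2 intensity. The 75th percentile over non-control probes was then subtracted on each array, so each level below is a log2 intensity relative to that percentile. A probe entered the tests when more than 1 in 2 of its spots were well above background by the scanner software on all 3 arrays of at least 1 group, which left 36039 of 75149 probes. No spot was saturated. For arrays, the number of arrays limits the precision.

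Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 mean per group and 12 residual degrees of freedom over all 18 arrays. P-values were adjusted by the Benjamini-Hochberg method over all tested probes in each comparison, and a probe was called at an adjusted p under 0.05. The comparisons were RS-FaDu minus FaDu at each time and averaged over the 3 times, 24 h and 48 h minus 0 h within each line, and the difference between the lines in each of these time changes (the line by time interaction). Probes called in the same direction at all 3 times were counted beside the number that independent lists would share. In data simulated on the 36039 probes with 50 changed probes of each size, 50% of changes of log2 1 and 90% of changes of log2 2 were recovered for the line difference at 0 h, 86% and 100% for the averaged difference, and 24% and 72% for the interaction at 24 h, with 7, 8 and 2 false calls. The simulated noise was independent between probes and had the same SD in all groups. These rates may therefore not hold for the 0 h arrays, which varied more than the 24 h arrays, or where many more probes change.

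The comparisons, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. The files name probes and not genes, and no table that pairs these probes with genes was used here. The gene lists fixed beforehand, the markers of other cell types, the fixed single genes and the named-gene rule could therefore not be run. In their place, the 2 highest and 2 lowest probes of the averaged line difference are named, among probes called in the same direction at all 3 times with all 3 RS-FaDu arrays on the same side of all 3 FaDu arrays at each time. RNA classes were read from the probe identifiers after the files were seen: 34235 Agilent catalogue probes, 38141 custom probes with p numbers, and smaller sets such as 306 for small nucleolar and Cajal body RNAs (snoRNA and scaRNA), 99 for transfer RNAs (tRNA) and 938 with the identifier imsncRNA. Each class was compared with all other probes by limma's camera (cameraPR on the moderated statistics with a preset correlation of 0.01, and camera with an estimated correlation), adjusted over all classes and comparisons together. All other settings of the class tests kept the preset correlation, so they do not test it. Where a named probe was not well above background on any array of a line at a time, its fold is a lower bound against the lowest level of any probe well above background on the same array, or against the probe's own level where that was higher.

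The only probes whose identifiers name genes were control-type probes for GAPDH and PGK1, of which the human ones were used, a pair for each gene near the 3′ and 5′ ends. They were chosen after the files were seen and tested with an exact permutation of the line labels within times (or of the time labels within lines), two-sided, with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Their 30 p-values over both lines or all times were adjusted together. Figures were drawn with matplotlib 3.10.9.

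The arrays lay on 5 slides and fell into 2 scan batches, with all 0 h and 24 h arrays in the first and all 48 h arrays in the second. A scan batch here holds the arrays scanned in the same month, so it does not resolve scan sessions within a month. Alternatives were other scalings (quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, the 75th percentile over the 10160 probes well above background on all 18 arrays), other filters on dim probes, outlier spots kept, an intensity trend with robust estimation, a fit of only the compared groups, the replicate number or the slide as a block, the deposited value table and each array left out in turn. The normexp correction was planned on mean spot intensities, and median intensities were used because the files read here had no mean column. Added after the data were seen were combinations of scaling and filter, fits within the slide that held both lines, a fit without the 3 arrays with the fewest spots above background, and all alternatives of the classes and of GAPDH and PGK1. Within each slide that held both lines at 1 time, 1 of the lines had a single array, so fits within a slide or with the slide as a fixed block assume that this array varied like the others and cannot separate what is particular to it from a line difference. No array was left out of the reported fit.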

Results

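Gene expression was compared between FaDu, a human hypopharyngeal carcinoma line, and RS-FaDu, its radioresistant derivative, both given 4 Gy and sampled at 0, 24 and 48 h, with 3 arrays per group and 18 in all. The series asks how long non-coding and messenger RNAs differ between the lines over the time after radiation. Each array held 175906 spots of non-control probes. The share of spots well above background ranged from 14.2% on RS-FaDu 24 h replicate 2 to 60.5% on FaDu 24 h replicate 3. The next lowest were FaDu 0 h replicate 3 with 21.9% and RS-FaDu 24 h replicate 3 with 22.1%. Probes well above background on all 3 arrays of a group numbered 17085 in FaDu and 21495 in RS-FaDu at 0 h, 23141 and 10657 at 24 h, and 34047 and 33831 at 48 h.

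**Figure D1:**
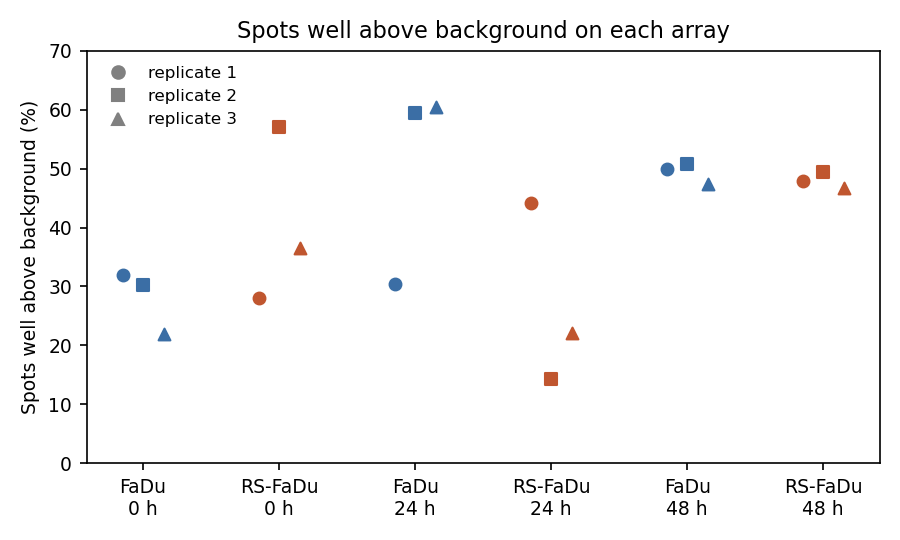
Percentage of non-control spots well above background on each of the 18 arrays (y axis, %) by line and time (x axis), 1 point per array with the marker giving the replicate. RS-FaDu 24 h replicate 2 lies lowest at 14.2%, and the 48 h arrays lie between 46.7% and 50.8%.

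Arrays of a group correlated with Pearson's r between 0.973 and 0.996 across probes, which are not independent replicates, and no 2 arrays held identical values. In a principal component analysis of the 10160 probes well above background on all 18 arrays, the first component held 60.74% of the variance and set the 0 h arrays (loadings between −0.49 and −0.20) apart from the 24 h and 48 h arrays (0.13 to 0.23). The second component held 20.83%. The third held 8.27% and separated the lines, with every RS-FaDu array between 0.20 and 0.27 and every FaDu array between −0.40 and −0.10.

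**Figure D2:**
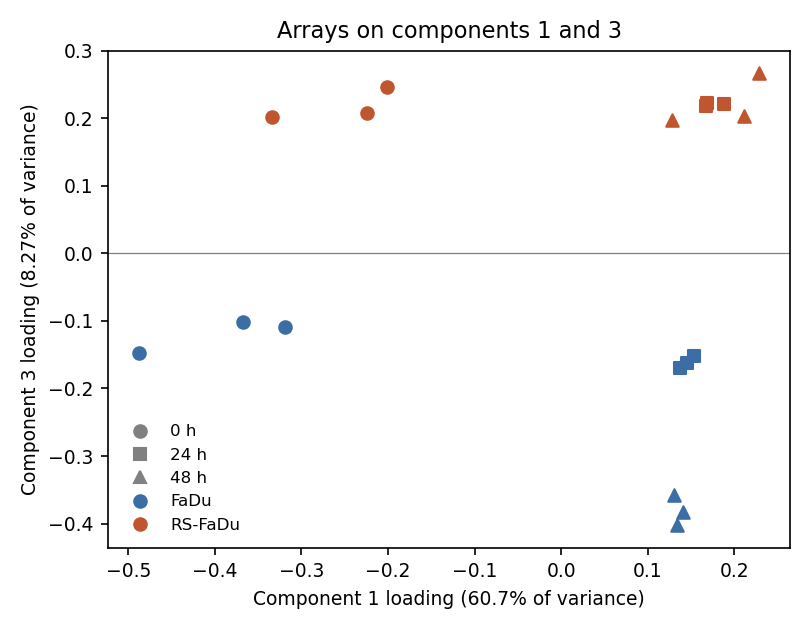
Loadings of the 18 arrays on component 1 (x axis, 60.7% of variance) and component 3 (y axis, 8.27% of variance), with colour for the line and marker for the time. The 0 h arrays lie left of −0.20 and the others right of 0.12 on component 1, and all 9 RS-FaDu arrays lie above 0 and all 9 FaDu arrays below it on component 3.

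The first question was which RNAs differed between the lines at every time. A_21_P0005630 was higher in RS-FaDu at all 3 times (averaged difference, limma adjusted p = 2.35e-08). Its level was 1.58 ± 0.16 (SD, n = 3) in RS-FaDu at 0 h and 0.22 ± 0.19 at 48 h, and it was not well above background on any FaDu array, so that RS-FaDu was at least 6.17-fold higher at 0 h and at least 13.2-fold higher at 48 h. A_33_P3238533 was also not well above background on any FaDu array (adjusted p = 7.33e-09 by limma). RS-FaDu was at least 2.63-fold higher at 0 h, where its level was 0.34 ± 0.21 (SD, n = 3), and at least 50.1-fold higher at 48 h, where it was 2.15 ± 0.34. At 24 h both probes were well above background on 2 of the 3 RS-FaDu arrays, with levels of 0.96 ± 0.23 and 1.22 ± 0.04.

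In the other direction, p33919 was well above background on every FaDu array and on no RS-FaDu array (averaged difference, limma adjusted p = 8.61e-08). Its FaDu level was 0.56 ± 0.05, 1.06 ± 0.16 and 1.21 ± 0.23 at 0, 24 and 48 h (SD, n = 3), and RS-FaDu was at least 7.44-fold, 3.43-fold and 24.0-fold lower. Probe p8814 was lower in RS-FaDu by a log2 difference of −3.24 (SE 0.42) at 0 h, with 4.90 ± 0.37 in FaDu and 1.65 ± 0.60 in RS-FaDu (n = 3, averaged difference, limma adjusted p = 4.81e-09). At 24 and 48 h it was well above background on 1 of the 3 RS-FaDu arrays each, with FaDu levels of 3.55 ± 0.23 and 2.31 ± 1.02. These probes were picked by their fitted averaged difference among probes called and separated at all 3 times, an order that rests in part on background levels, and the files give no gene for them.

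**Figure D3:**
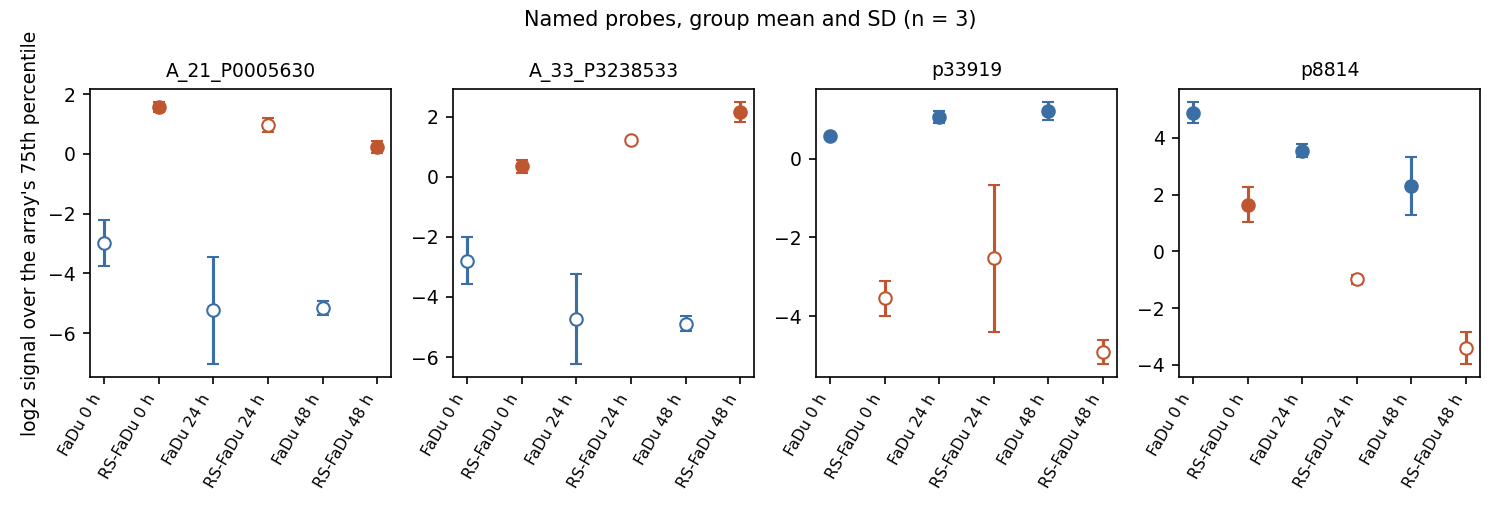
Level of each named probe in the 6 groups (y axis, log2 intensity over the array's 75th percentile, mean with SD of 3 arrays), filled where all 3 arrays were well above background and open elsewhere. FaDu points are open for both A_ probes at each time, and RS-FaDu points are open for p33919 at each time.

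In all, 1671 probes differed in the same direction at 0, 24 and 48 h, 663 of them higher and 1008 lower in RS-FaDu, where independent lists would share 31.8 and 54.2. Agilent catalogue probes made up 436 and 761 of them (of 21089 tested) and custom p-numbered probes 225 and 238 (of 13399 tested). Of the 210 tested snoRNA and scaRNA probes, 4 were lower at all 3 times. The counts were 1074 and 643 with the 75th percentile over bright probes, so that which direction held more probes depended on the scaling, and 91 and 150 with the slide as a fixed block. In total, 591 were shared in a fit of only the probes well above background on all 18 arrays, 761 with no filter on dim probes and 558 in fits of only the groups compared. Of the 1671, 151 higher and 288 lower probes were well above background on all 18 arrays.

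Averaged over the 3 times, 13691 probes differed between the lines, 6348 higher and 7343 lower in RS-FaDu, and 994 and 874 of these by 2-fold or more. Probes for snoRNAs and scaRNAs, which guide chemical changes to other RNAs, were lower as a class, with a median log2 difference of −0.23 against 0.03 for all other probes. Of 210 tested, 11 were higher and 83 lower (12 and 84 adjusted over the class alone), with camera adjusted p = 0.00159. With an estimated correlation the adjusted p was 0.822, and over 33 other settings it ranged from 1.27e-05 to 0.243. Among probes well above background on all 18 arrays the gap between the class and the others was −0.11 and missed the threshold. The gap between the 3′ and 5′ probes of GAPDH, a sign of RNA or labelling quality, was also lower in RS-FaDu on average (−0.35), while that of PGK1 was 0.43. All probes together gave 11252 higher and 4666 lower with the 75th percentile over bright probes, which moved the median of all probes by 0.16, and 2901 and 3721 with the slide as a fixed block. The count was 4814 among probes well above background on all 18 arrays.

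At 0 h, tRNA probes, for the RNAs that carry amino acids to the ribosome, were higher in RS-FaDu. Their median difference was 0.38 against −0.09 for the others, and limma called 15 of 70 higher and 0 lower (15 and 0 adjusted over the class alone, 18 and 1 at an unadjusted p under 0.05), with camera adjusted p = 9.25e-05. The adjusted p was 0.869 with an estimated correlation, which was 0.451 between tRNA probes, and at most 0.0305 over 22 other settings. The gap of 0.47 became 0.21 without FaDu 0 h replicate 2, 0.27 without RS-FaDu 0 h replicate 3, 0.79 without FaDu 0 h replicate 3 and 0.73 with the slide as a fixed block, so that its size rested on single arrays. Agilent catalogue probes lay lower than the others, with a gap of −0.19 (adjusted p = 0.00159, and 0.822 with an estimated correlation), which was −0.07 and missed the threshold with the slide as a fixed block and within a slide, and turned to 0.32 with no filter on dim probes. The medians for snoRNA and scaRNA probes were −0.27 against −0.08, with 7 higher and 36 lower, and the class missed the threshold (adjusted p = 0.141).

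In total 8236 probes differed between the lines at 0 h, 2845 higher and 5391 lower in RS-FaDu, 1088 and 1353 by 2-fold or more. The direction of the excess depended on the scaling, with 8298 higher and 1900 lower with the 75th percentile over bright probes (median of all probes moved by 0.37), 2603 and 1625 with quantile normalization (0.17) and 4268 and 2884 with normexp and quantile normalization. Among probes well above background on all 18 arrays the count was 3933. It was 3677 with no filter, 1181 in a fit of the 0 h arrays alone, 4932 without RS-FaDu 0 h replicate 1 and 4727 without RS-FaDu 0 h replicate 2. Over bright probes, pairs of arrays differed with an SD of log2 0.37 to 0.53 in FaDu and 0.28 to 0.40 in RS-FaDu at 0 h. At 24 h these were 0.15 to 0.22 and 0.14 to 0.17. The spread shared by all 18 arrays may thus understate that at 0 h. With the slide as a fixed block 691 probes were called, and limma called 0 within the slide that held 1 RS-FaDu and 3 FaDu arrays, where 2049 had an unadjusted p under 0.05 and the lone array was assumed to vary like the others.

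At 24 h, snoRNA and scaRNA probes were lower in RS-FaDu, with a median of −0.20 against 0.07 for the others. Of 210, 2 were higher and 16 lower (2 and 13 adjusted over the class alone, camera adjusted p = 0.00357). The adjusted p was 0.822 with an estimated correlation and ranged from 5.39e-07 to 0.169 over 22 other settings, with the call lost under quantile normalization (−0.18), with normexp and quantile normalization (−0.13) and among bright probes alone (−0.18). The gap of −0.27 became −0.95 with no filter on dim probes. The GAPDH gap between 3′ and 5′ probes was 0.27 in RS-FaDu and 0.47 in FaDu at 24 h, and that of PGK1 was 3.31 and 3.39. Limma called 0 of the 70 tRNA probes at 24 h, and 0 had an unadjusted p under 0.05. The tRNA median was −0.14 against 0.07 for the others.

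Over all probes, 5925 differed at 24 h, 3268 higher and 2657 lower in RS-FaDu, and 1912 and 808 by 2-fold or more. RS-FaDu replicates 2 and 3 had few spots above background, and 1571 of the 1912 probes that were 2-fold higher were not well above background on either, against 573 of the 808 that were 2-fold lower. Without RS-FaDu 24 h replicate 2 there were 1826 higher and 2174 lower, without replicate 1 5397 and 2614, and without replicate 3 2442 and 1783. Quantile normalization gave 2350 higher and 5274 lower, and normexp with quantile normalization 2696 and 4746. The count was 1545 among probes well above background on all 18 arrays, 3127 with no filter, 2351 (1046 higher, 1305 lower) without the 3 arrays with the fewest spots above background (which left 1 RS-FaDu 24 h array, assumed to vary like the others), 3579 without FaDu 24 h replicate 2 and 3430 without FaDu 24 h replicate 3. It was 1413 with the slide as a fixed block, and limma called 0 within the slide that held 3 RS-FaDu arrays and 1 FaDu array, where 5336 had an unadjusted p under 0.05 under the same assumption.

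At 48 h, snoRNA and scaRNA probes were again lower in RS-FaDu. Their median was −0.26 against 0.05 for the others, with 5 higher and 51 lower of 210 (5 and 51 adjusted over the class alone, camera adjusted p = 0.00155). The adjusted p was 0.822 with an estimated correlation and ranged from 0.00011 to 0.118 over 22 other settings. Probes for tRNAs were lower too, with a median of −0.27 against 0.05, 0 higher and 17 lower of 70 by limma (0 and 17 adjusted over the class alone, 1 and 21 at an unadjusted p under 0.05) and camera adjusted p = 0.0131. That p was 0.869 with an estimated correlation and 0.00221 to 0.0998 over 22 other settings. Both calls were lost among bright probes alone, where the medians were −0.26 against 0.002 for snoRNA and scaRNA probes and −0.32 against 0.002 for tRNA probes. The tRNA call was also lost with normexp and quantile normalization (−0.21 relative to the others, against −0.32) and without FaDu 48 h replicate 2 (−0.25). The gap between the 3′ and 5′ probes of PGK1, a sign of RNA or labelling quality, was 4.79 in RS-FaDu and 3.24 in FaDu at 48 h, and that of GAPDH was 0.62 and 1.45.

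In all, 9356 probes differed at 48 h, 4443 higher and 4913 lower in RS-FaDu, and 1553 and 2186 by 2-fold or more. The count was 4260 among probes well above background on all 18 arrays, 5548 with no filter, 4467 with the slide as a fixed block, and 7419 within the slide that held 3 RS-FaDu arrays and 1 FaDu array. Both slide counts rest on that 1 FaDu array, so what is particular to it cannot be separated from a line difference.

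**Figure D4:**
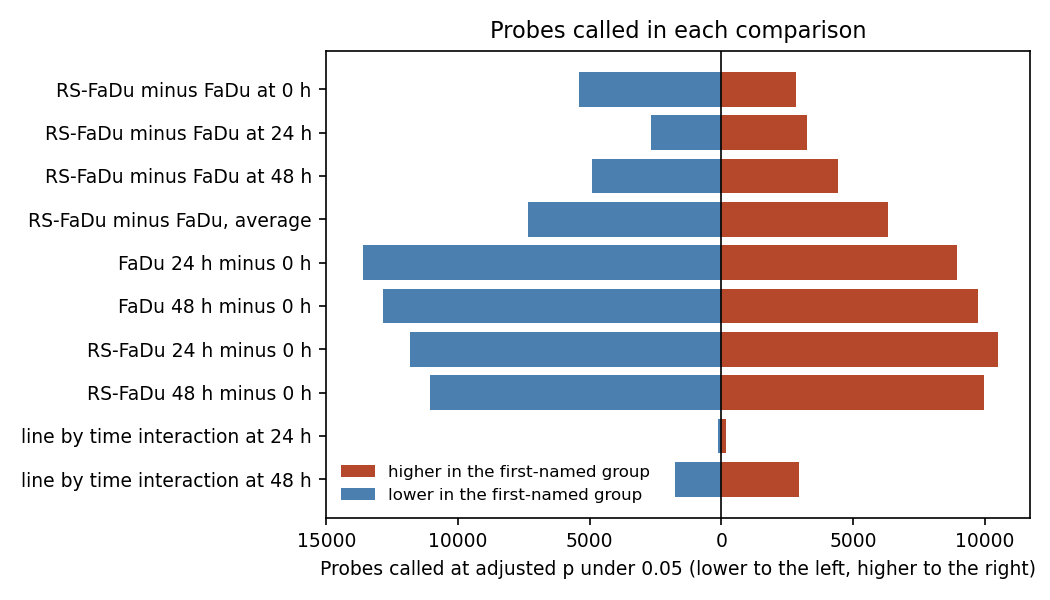
Number of probes called at adjusted p under 0.05 in each comparison (x axis, probes), with probes higher in the first-named group to the right of 0 and lower to the left. The time comparisons each called between 21037 and 22575 probes, and the interactions 310 at 24 h and 4721 at 48 h, and the balance of higher and lower probes depended on the scaling.

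The lines also differed in the 3′ probe of GAPDH, a glycolytic enzyme often used as a reference gene. Its 3′ probe was lower in RS-FaDu by an averaged log2 difference of −0.65, with an exact permutation p of 0.00025 (9 arrays per line, the smallest that the permutations can give, adjusted p = 0.0075 over 30 tests). The difference was −0.61 at 0 h, −0.23 at 24 h and −1.10 at 48 h, with all 3 RS-FaDu arrays below all 3 FaDu arrays at each time (exact permutation p = 0.1 each, the smallest that 3 against 3 allows). The averaged difference was −0.45 with quantile normalization and −0.48 with the 75th percentile over bright probes. At 0, 24 and 48 h it was −0.21, −0.22 and −0.91 with the former and −0.24, −0.17 and −1.04 with the latter. With quantile normalization the lines were no longer fully apart at 0 h (exact permutation p = 0.2). The control-type probes E1A_r60_1, E1A_r60_n9 and E1A_r60_a22 were also lower in RS-FaDu at 0 h (6.23 against 7.21, 5.98 against 7.08 and 3.66 against 3.97). At 24 h they stood at 4.07 against 4.50, 3.29 against 3.91 and 2.90 against 3.04, and at 48 h at 5.23 against 5.18, 4.33 against 4.47 and 2.93 against 2.79. A lower level in RS-FaDu at 0 and 24 h was thus not particular to GAPDH, and no test was run on these probes. The 5′ probe of GAPDH gave −0.30 (exact permutation p = 0.0912, adjusted p = 0.15), and passed the threshold only without RS-FaDu 48 h replicate 1 (−0.43). PGK1, another glycolytic enzyme, gave −0.04 with its 3′ probe (exact permutation p = 0.7995) and −0.47 with its 5′ probe (exact permutation p = 0.0248, adjusted p = 0.0469). The PGK1 5′ call was lost with quantile normalization (−0.37), with the 75th percentile over bright probes (−0.30), and without RS-FaDu 0 h replicate 1 (−0.40), RS-FaDu 0 h replicate 2 (−0.41) or FaDu 0 h replicate 1 (−0.42).

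The gap between the 3′ and 5′ probes of these genes, a sign of RNA or labelling quality, was also compared. The PGK1 gap was 4.79 ± 0.43 in RS-FaDu and 3.24 ± 0.34 in FaDu at 48 h (SD, n = 3), while the GAPDH gap was 0.62 ± 0.53 and 1.45 ± 0.06. At 0 h the PGK1 gaps were 2.85 ± 0.12 and 3.03 ± 0.21, and the GAPDH gaps 0.35 ± 0.09 and 0.37 ± 0.21. At 24 h they were 3.31 ± 0.10 and 3.39 ± 0.05 for PGK1, and 0.27 ± 0.07 and 0.47 ± 0.10 for GAPDH. Averaged over both lines the PGK1 gap rose by 0.41 to 24 h (exact permutation p = 0.005, adjusted p = 0.015) and by 1.08 to 48 h (exact permutation p = 0.015, adjusted p = 0.0346), and the GAPDH gap changed by 0.01 (exact permutation p = 0.945) and 0.67 (exact permutation p = 0.025, adjusted p = 0.0469). With quantile normalization these changes were 0.89 and 1.47 for PGK1 and −0.07 and 0.58 for GAPDH. The averaged line difference of the GAPDH gap was −0.35 (exact permutation p = 0.00925, adjusted p = 0.0252), and that of the PGK1 gap was 0.43 (exact permutation p = 0.095, adjusted p = 0.15).

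**Figure D5:**
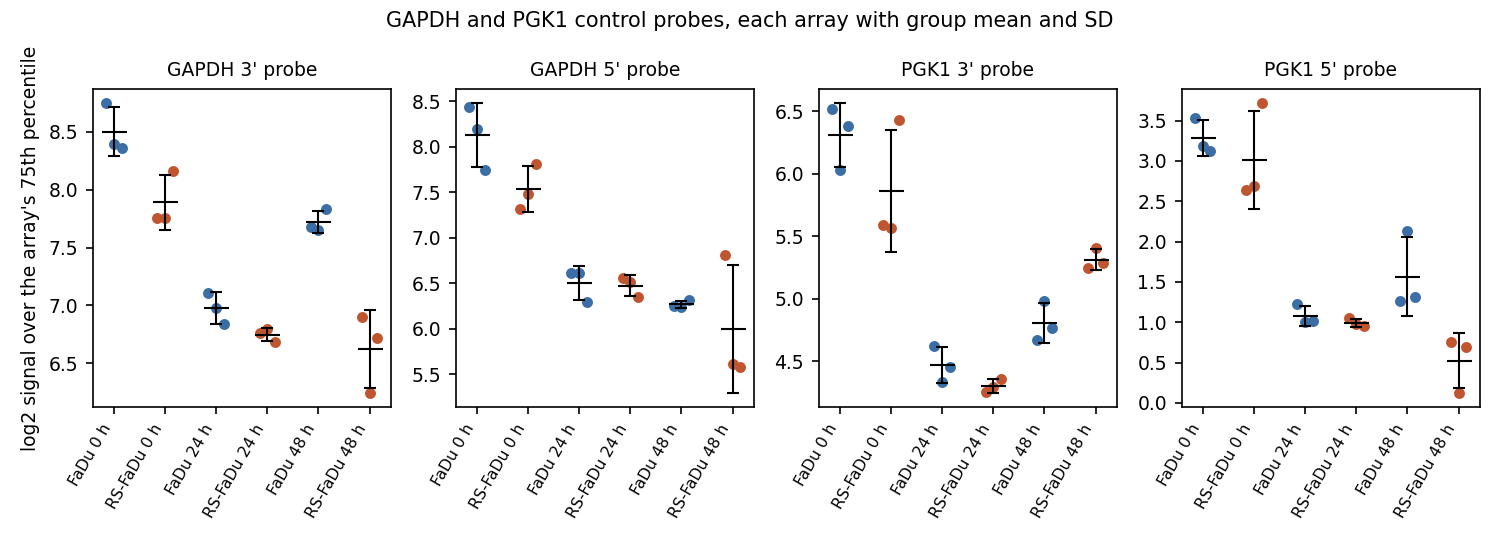
Levels of the GAPDH and PGK1 control-type probes (y axis, log2 intensity over the array's 75th percentile) in the 6 groups (x axis), 1 point per array with the group mean and SD (n = 3). The GAPDH 3′ probe lies between 8.36 and 8.74 in FaDu and between 7.75 and 8.16 in RS-FaDu at 0 h.

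The second question was what changed with time after radiation. From 0 h to 24 h and to 48 h, averaged over both lines, the GAPDH and PGK1 probes fell relative to the 75th percentile. The GAPDH 3′ probe changed by −1.33 and −1.02, the GAPDH 5′ probe by −1.34 and −1.70, the PGK1 3′ probe by −1.70 and −1.02 and the PGK1 5′ probe by −2.11 and −2.10 (exact permutation p = 0.005 each, the smallest of 400 assignments, adjusted p = 0.015). The size depended on the scaling. With the 75th percentile over bright probes the changes were −0.45 and −0.26 for the GAPDH 3′ probe, −0.45 and −0.93 for the GAPDH 5′ probe, −0.81 and −0.26 for the PGK1 3′ probe and −1.22 and −1.34 for the PGK1 5′ probe. With quantile normalization they were −0.56 and −0.39, −0.49 and −0.97, −0.76 and −0.19, and −1.65 and −1.66. The exact permutation p stayed at 0.005 except at 48 h for the 3′ probes, with 0.12 and 0.145 over bright probes and 0.04 and 0.27 with quantile normalization, for GAPDH and PGK1. The control-type probe E1A_r60_1 stood at 7.21 ± 0.34 (SD, n = 3) in FaDu and 6.23 ± 0.28 in RS-FaDu at 0 h, at 4.50 ± 0.24 and 4.07 ± 0.04 at 24 h, and at 5.18 ± 0.17 and 5.23 ± 0.39 at 48 h. A fall relative to the percentile was thus not particular to GAPDH and PGK1. Whether these falls come from the cells or from the reference and labelling was not tested.

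Probes for tRNAs fell from 0 h to 48 h in RS-FaDu. Their median change lay −1.63 from that of the other probes, with 5 higher and 60 lower of 70 (6 and 60 adjusted over the class alone, camera adjusted p = 8.72e-12). The adjusted p was 0.822 with an estimated correlation and at most 7.37e-06 over 20 other settings, in which the gap ranged from −1.77 to −0.73. In FaDu the tRNA gap from 0 h to 48 h was −0.94, with 8 higher and 52 lower (8 and 53 adjusted over the class alone, adjusted p = 0.0131, 0.869 with an estimated correlation). This FaDu call passed in 14 of 20 other settings, with gaps from −1.16 to −0.07. Among the settings that lost it were those without FaDu 0 h replicate 3 (−0.77), among bright probes alone (−0.51), with quantile normalization (−0.35) and with normexp and quantile normalization (−0.28). From 0 h to 24 h in RS-FaDu the gap was −0.92, with 6 higher and 44 lower (6 and 45 adjusted over the class alone, adjusted p = 0.00529, 0.869 with an estimated correlation). That call was lost with quantile normalization (−0.01), with normexp and quantile normalization (−0.17), among bright probes alone (−0.56) and with the slide as a fixed block (−0.48). Beside these falls the PGK1 gap between 3′ and 5′ probes went from 2.85 at 0 h to 3.31 at 24 h and 4.79 at 48 h in RS-FaDu, and from 3.03 to 3.39 and 3.24 in FaDu. The GAPDH gap went from 0.35 to 0.27 and 0.62 in RS-FaDu, and from 0.37 to 0.47 and 1.45 in FaDu, so the 2 genes did not move alike.

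Probes for snoRNAs and scaRNAs fell from 0 h to 48 h in RS-FaDu, with a gap of −0.60 to the others and 26 higher and 112 lower of 210 (29 and 112 adjusted over the class alone, camera adjusted p = 0.0033, 0.822 with an estimated correlation), beside the same rise of the PGK1 gap. The GAPDH gap went from 0.35 to 0.62 over that time. Over 20 other settings the gap of the class to the others ranged from −0.68 to −0.18, with a camera adjusted p of at most 0.259.

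The 13399 custom p-numbered probes rose from 0 h to 24 h relative to the others, which are mostly Agilent catalogue probes. The gap was 0.46 in FaDu, with 3774 higher and 3292 lower (3677 and 3210 adjusted over the class alone, camera adjusted p = 0.000336), and 0.46 in RS-FaDu, with 4720 and 2650 (4535 and 2567, adjusted p = 0.000411). From 0 h to 48 h in FaDu it was 0.49, with 4173 and 3153 (4048 and 3091, adjusted p = 0.00159). With an estimated correlation the adjusted p was 0.822 for all 3. With no filter on dim probes the FaDu gaps turned to −0.26 and −0.52. The RS-FaDu call at 24 h and the FaDu call at 48 h were lost with quantile normalization (0.14 and 0.34) and with normexp and quantile normalization (0.12 and 0.18), and the latter also with quantile normalization and only bright probes (0.29). The PGK1 gap between 3′ and 5′ probes rose over the same times, by 0.41 to 24 h and 1.08 to 48 h averaged over both lines. The GAPDH gap changed by 0.01 and 0.67.

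Probes with the identifier imsncRNA had median changes from 0 h to 24 h of 0.20 in FaDu and 0.32 in RS-FaDu, where custom p-numbered probes had 0.08 and 0.29, and no test compared the 2 classes, so a rise particular to imsncRNA probes is not shown. Against all other probes the gap was 0.37 in FaDu, with 173 higher and 103 lower of 495 (169 and 103 adjusted over the class alone, adjusted p = 0.00499, 0.822 with an estimated correlation). In RS-FaDu it was 0.31, with 177 higher and 87 lower (168 and 86 adjusted over the class alone, adjusted p = 0.0131, 0.822 with an estimated correlation). The RS-FaDu gap was −0.03 with no filter on dim probes and missed the threshold with quantile normalization (0.18) and with normexp and quantile normalization (0.09). Both imsncRNA calls were lost with the slide as a fixed block (0.25 in FaDu and 0.28 in RS-FaDu), and they and the snoRNA call in RS-FaDu to 48 h were lost among bright probes alone. There the imsncRNA medians were −0.39 against −0.63 for the others in FaDu and −0.29 against −0.43 in RS-FaDu. The snoRNA and scaRNA median was −0.89 against −0.41.

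Over all probes, 22565 changed from 0 h to 24 h in FaDu (8946 higher, 13619 lower) and 22329 in RS-FaDu (10509 and 11820). From 0 h to 48 h the counts were 22575 in FaDu (9735 and 12840) and 21037 in RS-FaDu (9972 and 11065). The lines shared 6958 higher and 10842 lower probes at 24 h, with 97 called in opposite directions, and 6836, 9191 and 391 at 48 h. The balance of directions depended on the scaling. With the 75th percentile over bright probes the FaDu counts were 21714 and 5198 at 24 h and 21716 and 4896 at 48 h, with the median of all probes moved by 1.04 and 0.92, and the RS-FaDu counts were 21207 and 5235 (0.73) and 18915 and 5585 (0.61). With quantile normalization they were 10433 and 8998 and 10917 and 8024 in FaDu (0.27 each), and 7931 and 12165 and 9116 and 7873 in RS-FaDu. With normexp and quantile normalization they were 11515 and 9905 and 12119 and 9012 in FaDu, and 8576 and 11550 and 10219 and 8598 in RS-FaDu.

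Among probes well above background on all 18 arrays, the 4 time comparisons called 8184 and 8062 in FaDu and 7654 and 7553 in RS-FaDu. With the slide as a fixed block, 9808 probes were called from 0 h to 24 h in FaDu and 9711 in RS-FaDu. The changes from 0 h to 48 h could not be estimated in that fit, and since all 48 h arrays were in another scan batch, time and scan batch cannot be told apart there.

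The third question was whether the lines changed differently with time. The change of the tRNA probes from 0 h was more negative in RS-FaDu than in FaDu. Relative to the other probes, their interaction was −0.76 at 24 h (adjusted p = 2.05e-11) and −0.74 at 48 h (adjusted p = 3.04e-10), by camera. Over 27 other settings each, all with the preset correlation, the camera adjusted p was at most 1.04e-05 and 2.58e-06. The gaps ranged from −1.45 (no filter on dim probes) to −0.44 (without FaDu 0 h replicate 2) and from −1.07 to −0.51. With an estimated correlation, 0.451 between tRNA probes, the camera adjusted p was 0.822 for both. The 27 settings thus do not test the preset correlation, on which both calls rest. Single tRNA probes gave 0 higher and 0 lower at 24 h by limma (0 and 0 adjusted over the class alone, 1 and 15 at an unadjusted p under 0.05) and 0 higher and 14 lower at 48 h (0 and 14 adjusted over the class alone, 1 and 28 unadjusted). Both interactions subtract the same line difference at 0 h, where the tRNA gap was 0.47 and its size rested on single arrays. The tRNA gap between the lines was −0.20 at 24 h and −0.32 at 48 h, so the interactions are not separate from the 0 h result. The PGK1 gap between 3′ and 5′ probes moved with the tRNA probes at 48 h, with an interaction of 1.73, and gave 0.11 at 24 h (exact permutation p = 0.57). The GAPDH gap went the other way, with −0.82 at 48 h (exact permutation p = 0.08) and −0.18 at 24 h (exact permutation p = 0.285).

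The PGK1 3′ probe gave 0.95 at 48 h (exact permutation p = 0.025, adjusted p = 0.0469) and missed the threshold with quantile normalization (0.67, exact permutation p = 0.065) and with the 75th percentile over bright probes (0.64, exact permutation p = 0.06). The PGK1 gap gave 1.73 (exact permutation p = 0.015, adjusted p = 0.0346). Agilent catalogue probes lay 0.16 above the others at 48 h (adjusted p = 0.0156, 0.822 with an estimated correlation), which missed the threshold with the 75th percentile over bright probes (0.16), with quantile normalization (0.16), with normexp and quantile normalization (0.10), with the slide as a fixed block (0.02), without RS-FaDu 0 h replicate 1 (0.14) and without RS-FaDu 48 h replicate 1 (0.12), and turned to −0.34 with no filter on dim probes.

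In all, the interaction called 310 probes at 24 h (189 higher, 121 lower) and 4721 at 48 h (2953 and 1768). The balance depended on the scaling, with 70 and 324 at 24 h and 1186 and 3266 at 48 h with the 75th percentile over bright probes, which moved the medians by −0.31, and with 125 and 454 and 1403 and 2135 with quantile normalization. With normexp and quantile normalization the counts were 214 and 1046 and 1979 and 2758. The count at 24 h was 64 without FaDu 24 h replicate 2, 71 without FaDu 24 h replicate 3, 72 without RS-FaDu 0 h replicate 2, 125 without RS-FaDu 24 h replicate 3, 170 without RS-FaDu 24 h replicate 2, 907 without FaDu 0 h replicate 3 and 2636 without RS-FaDu 24 h replicate 1. The count at 48 h was 2702 without RS-FaDu 0 h replicate 2. With the slide as a fixed block the interactions called 10 and 401 probes, and with no filter on dim probes 10 and 1171.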

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

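Chosen after the results were seen were the tests of the 2-fold changes at 24 h, of the spread of signals at 0 h by variance, of scan batch, of slides along the first component and of slides for the shared line difference, while the tests of RNA classes and of GAPDH and PGK1 were chosen after the files were seen. In the 6 groups of 3 arrays no single array was tested as an outlier.

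More probes were called higher than lower in RS-FaDu at 24 h (55.2% of 5925), and RS-FaDu 24 h replicates 2 and 3 had high background. Refitted on probes well above background on all 18 arrays, 45.8% were higher, a fall just inside the bound of 10 percentage points set beforehand, and the share was 45.6% without replicate 2, 57.8% without replicate 3, 67.4% without replicate 1 and 44.5% with only replicate 1 (and without FaDu 0 h replicate 3), so high background cannot be told apart from a line difference for the calls as a whole. For the 2-fold changes, 56.7% were higher among called probes well above background on all 18 arrays, against 70.3% among all called. The same share fell from 44.6% to 24.9% at 0 h and from 41.5% to 28.4% at 48 h, so the drop is not particular to these arrays and decides little. Their floor was raised, with a lowest signal of 110.45 and 61.11 on replicates 2 and 3, against 22.22 or less on the FaDu 24 h arrays. Control-type probes E1A_r60_3 and E1A_r60_a104 were well above background on no array. At 24 h they stood at −2.5 ± 1.8 each in RS-FaDu, and at −5.0 ± 1.6 and −4.3 ± 1.0 in FaDu (SD, n = 3). Background thus lifted these probes without signal in RS-FaDu. How many of the 2-fold calls it accounts for was not tested, and a line difference is not excluded. The cell line itself, which is the study's own group, stays open as an untested biological explanation.

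The 0 h arrays lay apart from the 24 h arrays. A wider spread of signals at 0 h is argued against as the whole cause, since with 1 distribution given to all arrays over bright probes 88.8% of the variance between the FaDu 0 h and 24 h arrays still lay between the times (89.5% in RS-FaDu), against at most 17.8% for other splits. The test set beforehand, the share of probes called for FaDu 24 h minus 0 h with quantile normalization and only bright probes (1.19 times the reported share, over other probes, and 0.924 times the count on the same probes), decides little, as 5199 of 7891 calls kept their sign there and 564 reversed, so the direction of single calls stays open to the scaling. All 0 h arrays (100%) shared a scan batch with the 24 h arrays, which argues against a difference between scan months. It cannot address scan sessions within a month. Slide is argued against because on the slide with 2 RS-FaDu 0 h and 2 FaDu 24 h arrays the pairs lay 0.35 apart on the first component, 15.7 times the widest range within a pair (0.02), although line and time differ together there. Time after radiation may account for the pattern as a hypothesis. As no unirradiated sample was measured, an effect of radiation cannot be told apart from a change with time alone. RNA handling or labelling by time point also stays open.

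The same probes differed between the lines at all 3 times. Chance overlap is argued against, since 1671 probes were shared where independent lists would share 86.0, a ratio of 19.4. The 3 lists share no array but share 1 estimate of the spread per probe, which the expected number does not allow for. A shared spread would raise calls in opposite directions too. Those numbered 75 for 0 and 24 h, 396 for 0 and 48 h and 71 for 24 and 48 h, where 699, 1052 and 773 were expected. Slide is argued against as the whole cause, since the slides of the 48 h arrays held no other time and with the slide as a fixed block 343 probes were shared in direction by 0 h and 48 h where 44.0 were expected, a ratio of 7.79, and 690 by 24 h and 48 h where 86.8 were expected (7.95). In that fit 1669 of the 1671 (99.9%) kept their averaged call, which decides little since they were chosen for it, and 6377 of all 13691 averaged calls and 241 shared probes were left, each within-slide difference resting on 1 array of a line. A lasting difference between the lines is a hypothesis consistent with these values, found and tested on the same arrays.

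Other splits of the arrays were compared with the real groups. For the line differences at single times and the changes with time there are 10 splits of 6 arrays, too few for a share under 0.05, and 1 of the 10, the real one, called as many probes in each. The real and the highest other counts were 8236 and 1487 for the lines at 0 h, 5925 and 123 at 24 h, 9356 and 14 at 48 h, 22565 and 0 for FaDu from 0 h to 24 h, 22575 and 1 for FaDu to 48 h, 22329 and 137 for RS-FaDu to 24 h, and 21037 and 0 for RS-FaDu to 48 h. For the averaged line difference, 1 of 100 splits, the real one, called as many (13691, highest other 940), the smallest share that 100 splits can give. This argues against a chance split of these arrays. It cannot tell the cell line apart from slide or handling, and the replicates may be technical.

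The lines differed in their change from 0 h to 24 h at 310 probes and to 48 h at 4721 probes by a test of the difference itself. For 24 h, 11 of 100 splits called as many, with a highest other count of 2656, so chance is not excluded. For 48 h, 4 of 100 splits called as many, with a highest other count of 11553. Neither share decides the question, since the other splits carry the line differences and do not stand for data without an interaction. At 48 h the highest count has a structure behind it: splits that exchange the lines at 1 time test the sum of the line differences, which by itself called 11544 probes for 0 and 48 h. For 24 h that sum called 10756 probes, far from the highest count drawn, and what raised the counts of the other splits was not tested.

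Tests of the difference in change also called single results. By 48 h the fitted interaction was 3.91 for A_33_P3238533, which was at background on every FaDu array, and −2.48 for p8814, which was well above background on 1 of 3 RS-FaDu arrays, so neither value measures how far the changes differed. Against the other probes, tRNA probes gave −0.76 at 24 h and −0.74 at 48 h, Agilent catalogue probes 0.16 at 48 h and custom p-numbered probes −0.16 at 48 h. These class calls rest on the preset correlation, and with an estimated correlation the camera adjusted p was 0.822 for tRNA at both times, 0.822 for Agilent catalogue and 0.869 for custom p-numbered probes. The PGK1 3′ probe gave 0.95 and the PGK1 gap between its 3′ and 5′ probes 1.73 at 48 h.

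Some control-type probes, which no test of the results used, were well above the negative controls on all 18 arrays. The lowest log2 level over the negative controls on any array was 2.65 for the DCP probes (9 of 18 probes), 3.82 for the E1A_r60 probes (3 of 10), 5.79 for GE_BrightCorner and 4.14 for Rat-GAPDH_5.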

How the results depend on the processing

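The settings added after the data were seen were normexp on median signals, both combinations of scaling and filter, the fit without the 3 arrays with the fewest spots above background, the fit within a slide, and all settings of the RNA classes and of GAPDH and PGK1. Of 268 alternative values of the 11 counts, 198 lay within 1.5 times the reported count. Of 427 alternative values of class shifts 352 kept direction and side of the threshold, of 120 for GAPDH and PGK1 110 did, and of 120 for the 4 named probes all did. With an estimated correlation all 18 class shifts lost their call (camera adjusted p of 0.822 or higher). The other class values kept the preset correlation and do not test it. The named probes were picked for large differences called at all 3 times, so their count decides little. Where no reason is named, the cause was not tested. Signal over background limits all counts: fewer probes entered under the strict filter, which by itself lowers them.

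Order below: line difference at 0 h, 24 h, 48 h and averaged, FaDu to 24 h and 48 h, RS-FaDu to 24 h and 48 h, interaction at 24 h and 48 h, and shared over 3 times, where each changed by over 1.5 times. Quantile normalization gave 4228 for the lines at 0 h and 579 for the interaction at 24 h. That interaction was 1260 with normexp on median signals, 563 with an intensity trend and robust estimation and 1372 with the slide as a random block. With no filter the lines gave 3677, 3127 and 5548, the interactions 10 and 1171 and the shared set 761. With only probes well above background on all 18 arrays (fewer tested) the lines gave 3933, 1545, 4260 and 4814, FaDu 8184 and 8062, RS-FaDu 7654 and 7553 and the shared set 591. With that filter and quantile normalization the lines gave 2456, 2246, 5092 and 5218, FaDu 7558 and 7322, RS-FaDu 7117 and 7360, the interaction at 24 h 205 and the shared set 725. With that filter and the 75th percentile over the same probes the lines gave 3369, 1627, 4496 and 5100, FaDu 8004 and 7566, RS-FaDu 7402 and 7359, the interactions 135 and 2917 and the shared set 637. With only the groups compared the lines at 0 h gave 1181, the interactions 21 and 3062 and the shared set 558. The lines gave 6044 at 24 h and 13333 at 48 h in these fits, so fewer arrays alone do not account for the fall at 0 h.

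With the slide as a fixed block the lines gave 691, 1413, 4467 and 6622, FaDu and RS-FaDu to 24 h 9808 and 9711, the interactions 10 and 401 and the shared set 241, while the changes to 48 h could not be estimated. Within the slide that held both lines limma called 0 at 0 h and 0 at 24 h (4 arrays each, 2049 and 5336 at an unadjusted p under 0.05). In both kinds of slide fit 1 line had a single array in the slide compared, assumed to vary like the others. Without the 3 arrays with the fewest spots above background the lines at 24 h gave 2351, from 1 RS-FaDu 24 h array assumed to vary like the others, and the interaction at 48 h 7092. The replicate number as a block (replicate block) gave 7623 for the lines at 0 h and 208 for the interaction at 24 h, within 1.5 times like its other counts, and replicate numbers did not pair the arrays. Gene lists, cell type markers and named genes were not run, for want of gene names, and normexp on mean signals was not run.

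An array outside the compared groups also moves a count, through the shared spread. The lines at 48 h gave 10643 without FaDu 0 h replicate 1, and the interaction at 24 h 180 without RS-FaDu 48 h replicate 2. The values that follow are for arrays of the compared groups only. Leaving out 1 of these at a time, the lines ranged from 4727 to 10241 at 0 h, 3430 to 8011 at 24 h, 6440 to 8124 at 48 h and 11933 to 15372 averaged, FaDu from 20628 to 23336 to 24 h and 20254 to 23830 to 48 h, RS-FaDu from 18837 to 22638 and 17938 to 20139, the interactions from 64 to 2636 and 2702 to 6161, and the shared set from 1252 to 2016. Moved by over 1.5 times were the lines at 0 h without RS-FaDu 0 h replicate 1 (4932) or 2 (4727), the lines at 24 h without FaDu 24 h replicate 2 (3579) or 3 (3430), the interaction at 24 h without RS-FaDu 24 h replicate 1 (2636), 2 (170) or 3 (125), FaDu 24 h replicate 2 (64) or 3 (71), RS-FaDu 0 h replicate 2 (72) or FaDu 0 h replicate 3 (907), and the interaction at 48 h without RS-FaDu 0 h replicate 2 (2702).

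With no filter the shift of Agilent catalogue probes turned to 0.32 for the lines at 0 h and −0.34 for the interaction at 48 h, and that of imsncRNA probes for RS-FaDu to 24 h to −0.0308. That of custom p-numbered probes turned to −0.26 for FaDu to 24 h and −0.52 for FaDu to 48 h. The averaged PGK1 3′ difference, not called, turned to 0.14 with quantile normalization, 0.12 with the 75th percentile over bright probes, 0.0074 without RS-FaDu 0 h replicate 1 and 0.0108 without RS-FaDu 0 h replicate 2, in a range from −0.1322 to 0.0108 over the arrays left out in turn.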

Other observations

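The values here belong to control-type probes and were looked at after the files were seen. The E1A_r60 probes did not move alike between times. E1A_r60_a97 stood at 3.91 ± 0.51 in FaDu and 2.35 ± 0.45 in RS-FaDu at 0 h, at −0.27 ± 0.22 and −1.07 ± 0.23 at 24 h, and at 0.30 ± 0.15 and −0.78 ± 0.29 at 48 h (log2 over the 75th percentile, SD, n = 3). E1A_r60_n9 stood at 7.08 ± 0.29 and 5.98 ± 0.36 at 0 h and at 3.91 ± 0.22 and 3.29 ± 0.08 at 24 h. E1A_r60_a22 stood at 3.97 ± 0.18 and 3.66 ± 0.09 at 0 h and at 3.04 ± 0.07 and 2.90 ± 0.05 at 24 h. No test was run on these differences.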
